A study of Homo sapiens with 24 samples.

How the data were processed

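The series holds a massively parallel reporter assay of single-base variants in human 3′ untranslated regions, linked by the series title to neurological disorders. Each 3′ UTR fragment was carried by a reporter plasmid, once with the reference base and once with each alternative base, and the pool was delivered with a lipid transfection reagent. The cells were SH-SY5Y, a human neuroblastoma line, and a microglia line immortalised with the SV40 large T antigen. Plasmid DNA and polyadenylated RNA were sequenced from 6 biological replicates of each line, which gave 4 groups of 6 libraries (24 libraries). Per the labels' protocols, RNA was reverse transcribed with a reporter-specific primer that carried a unique molecular identifier, and the 6 transfections were told apart by barcodes.

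The deposited table holds counts per variant and allele for each library, with no scaling for depth. Per the submitters' processing notes the tools were cutadapt 2.7, UMI-tools 1.0.0, Bowtie2 (version not given in the sources used here) and SAMtools 1.10, and the genome build was hg38. The labels describe the molecular identifier for RNA, and whether the DNA counts were also collapsed by an identifier is not given in the sources used here. The strand on which the alleles are written and the mapping settings are also not given in the sources used here. The reference and alternative oligos of a variant differ by a single base, so a read with an error at that base could be counted for the other allele, and near-identical oligos (of HLA genes, for example) could share reads.

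The table listed 13515 variants of 11265 SNPs in 1637 genes. It held 11265 reference and 13515 alternative oligos, 24780 in all, and 147 variants had no count in any library. Of the SNPs, 9244 had 1 alternative allele, 1792 had 2 and 229 had 3. The alternative alleles of a SNP share the counts of its reference oligo, so their tests are not independent. Gene names are those of the table. They were looked up in the RefSeq annotation of the same genome build (GRCh38.p14), where 1551 were current symbols, 73 were older symbols of 1 gene, 4 were older symbols of several genes and 9 did not match. The coordinates given are those of the gene in that annotation, since the table gives no position for the SNP.

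Allelic effects were tested with edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3). Each library entered as a reference and an alternative column, with the library as a block, and the coefficient tested was the log2 ratio of alternative to reference in RNA over the same ratio in DNA. A positive value means that the alternative allele was more abundant in RNA than its plasmid share predicts. Reporter activity was the log2 ratio of RNA to DNA of reference oligos, scaled with TMM over all oligos, and is therefore relative to the typical oligo of the pool. It describes a reporter with a fragment of the named gene's 3′ UTR, not the expression of that gene. Differences between cell lines were interaction terms fitted over all 24 libraries, given as microglia minus SH-SY5Y. Variants or oligos entered a test if each allele had a mean of at least 10 DNA counts per library in that cell line. P-values were adjusted by Benjamini-Hochberg over the variants or oligos tested, with a threshold of 0.05. The ± values are standard deviations of log2 ratios over the 6 RNA replicates, each taken against the mean log2 ratio of the DNA libraries with a pseudocount of 0.5. The effect itself comes from the fit.

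The named variants followed a rule set before the data were examined. Per cell line it took the 12 highest and 12 lowest allelic effects past the threshold with the same sign in all 6 replicates, at most 1 variant per gene and direction. Some of the variants and oligos it selects are not reported here. For each of 15 gene lists it took up to 3 variants past the threshold in both lines in the same direction. It took the 6 highest and 6 lowest reference oligos for activity, and the 8 highest and 8 lowest for each difference between lines. The gene lists were also fixed then: alcohol and aldehyde metabolism; GABA and glutamate receptors; monoamine, opioid, cannabinoid and cholinergic signalling; HLA and antigen presentation; cytokine and innate immune signalling; Alzheimer disease, Parkinson disease, ALS and frontotemporal dementia, psychiatric, and autism and epilepsy genes; RNA-binding and microRNA proteins; lysosome and autophagy; synaptic vesicle and scaffold; zinc finger proteins; and histones. A list was tested with a two-sided Fisher's exact test of its share of called variants against all other tested variants, adjusted over the 15 lists. Planned tests of sequence motifs gained or lost were not run, because they need the fragment sequences, which were not used here. Only the gain or loss of a G or C was tested (two-sided permutation test, 100000 resamples).

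The statistical code was tested on simulated counts drawn from the means and library sizes of the real data, with 200 items changed by known sizes. All oligos of a group were given the same spread, taken from oligos with a mean of at least 100 DNA counts. For allelic effects in SH-SY5Y, 10% of changes of log2 1 and 74% of changes of log2 2 were recovered, and in microglia 76% and 100%. For activity the shares were 36% and 100% in SH-SY5Y and 100% and 100% in microglia. For the difference in allelic effect between lines they were 8% and 64%, and for the difference in activity 14% and 98%. False calls among unchanged items were 0 of 12759 for allelic effects in SH-SY5Y and 5 of 12747 in microglia, 2 of 10771 and 5 of 10764 for activity, 4 of 12718 for the difference in allelic effect and 5 of 10744 for the difference in activity. Because rare oligos were given the spread of common ones, these rates may not hold for variants with a rare allele.

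Alternatives tried were DESeq2 1.42.0, limma 3.58.1 on log2 ratios with inverse-variance weights, other scaling factors, no DNA filter, a minimum of 50 DNA counts, removal of the median effect, alternative-allele oligos for activity, the replicate number as a block, and each replicate left out in turn. After the data were seen, a minimum of 200 DNA counts, robust empirical Bayes, each replicate left out of the differences between lines, and subtraction of reads shared between libraries were added. Other groupings of the same libraries were fitted as well, 100 for each test within a cell line and 40 for each difference. Figures were drawn with Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9. Where an RNA count was 0, the fold is a lower bound taken against 3 counts over the group, and where it was 1 to 3 the fold is given with an exact 95% interval. Both cover counting error only.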

Results

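The data describe how single-base changes in 3′ UTR fragments altered the abundance of reporter RNA in SH-SY5Y neuroblastoma cells and in immortalised microglia. Each line contributed 6 DNA and 6 RNA libraries. Total counts ran from 16556722 to 19101103 in SH-SY5Y DNA, from 11764547 to 18100832 in SH-SY5Y RNA, from 12154918 to 17570853 in microglia DNA and from 7018516 to 10437069 in microglia RNA. The median count per oligo lay between 348 and 539 in the SH-SY5Y RNA libraries and between 215 and 327 in the microglia RNA libraries. The 6 libraries of a group are biological replicates per the labels. Any 2 of them differed by more than counting noise (lowest chi-square per degree of freedom 4.25), where each count is taken as a separate molecule. Replicate spread differed between groups. Over 22553 oligos with at least 100 DNA counts, the coefficient of variation beyond counting error was 44.1% in SH-SY5Y RNA and 17.8% in microglia RNA, against 7.79% and 18.6% in the DNA of the same lines. Correlations between replicates were 0.752 to 0.841 for SH-SY5Y RNA and 0.921 to 0.961 for microglia RNA.

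**Figure D1:**
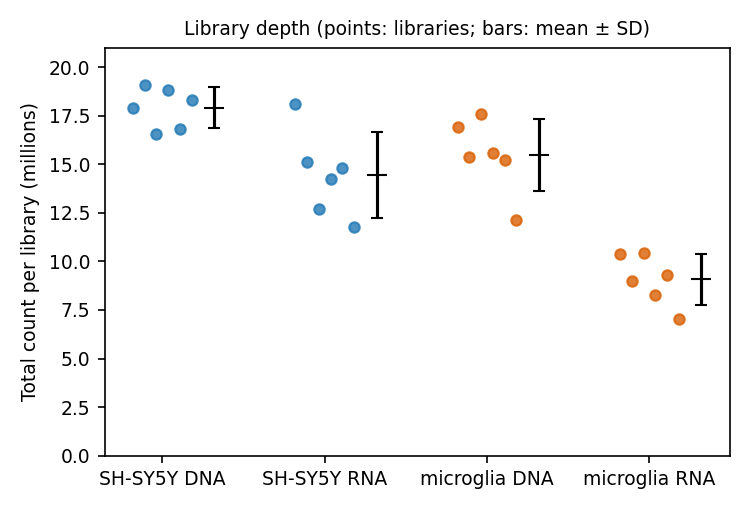
Total count per library for the 4 groups. Points are the 6 libraries of each group and bars are the mean ± SD, and the microglia RNA libraries were the shallowest.

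The comparison of alleles asks which 3′ UTR variants change reporter RNA in a given cell line. In SH-SY5Y the reporter carrying the G allele of STAT6 rs324015 A>G was higher in RNA than its plasmid share predicts by log2 3.39 ± 0.28 (SD, n = 6). STAT6, the transcription factor of interleukin-4 signalling, lies on chromosome 12 from 57095408 to 57111362. The G allele of PDLIM5 rs1139697 T>G, in a gene for a PDZ and LIM domain scaffold protein (chromosome 4, 94451942 to 94668223), was 13.0-fold higher (log2 3.70 ± 0.27). Higher alternative alleles were also measured for TTYH3 rs114755822 G>A (log2 2.20 ± 0.85; chromosome 7, 2631986 to 2664802), SLC39A8 rs151371 G>A (1.75 ± 0.52; chromosome 4, 102251041 to 102345482), which encodes a zinc and manganese importer, and SFTA2 rs2532925 C>T (1.22 ± 0.39; chromosome 6, 30931353 to 30932170). The alternative allele of ADH1C rs2298753 A>C, in an alcohol dehydrogenase gene (chromosome 4, 99336497 to 99352746), was lower (log2 -1.59 ± 0.45).

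Among 13031 variants tested in SH-SY5Y, 52 passed the threshold, 27 with a higher and 25 with a lower alternative allele. The median size was log2 1.49 among these, and 1137 variants had an unadjusted p under 0.05. The other named higher effects were GNE rs7048468 C>A (log2 4.57 ± 0.64), in the gene for the rate-limiting enzyme of sialic acid synthesis, LMO7 rs9544054 C>T (3.83 ± 2.12), KCTD2 rs73367072 G>C (3.77 ± 1.24), AATK rs7220721 G>A (3.19 ± 0.90), SPTSSB rs163327 T>A (1.83 ± 0.85), ATG13 rs7113453 G>A (1.54 ± 0.77) and C16orf62 rs116582019 C>A (1.54 ± 0.83). C16orf62 is now named VPS35L, a subunit of an endosomal recycling complex, and ATG13 is a subunit of the kinase complex that starts autophagy. GNE, LMO7, KCTD2 and AATK had a rare reference allele in the plasmid pool, and most of the largest lower effects had a rare alternative allele. BBS9 rs3779239 G>A had 0 alternative counts in RNA over all 6 replicates, with a mean of 11.8 in DNA, so the allele was at least 30.3-fold lower. RPS6KL1 rs56707537 G>C had 2 such counts (lower by 11.1-fold to 331-fold, 95% interval) and CDHR5 rs61877857 T>C had 3 (23.9-fold, 8.15 to 116). The lower effects of SLC9B1 rs6823625 A>G (log2 -5.10 ± 1.26), RDH13 rs2569514 C>T (-4.51 ± 1.83), FBLN1 rs74388276 C>T (-4.38 ± 0.88), TANC2 rs114844338 C>A (-4.32 ± 0.98), BRD2 rs73409643 C>A (-4.31 ± 1.27), ADAMTSL4-AS1 rs35900369 A>G (-4.12 ± 0.87), GIGYF1 rs221790 C>T (-4.10 ± 0.95) and MTA3 rs13418278 G>A (-3.77 ± 1.61) rested on 4 to 16 alternative counts in RNA. ZFP64 rs79646797 G>T was lower by a smaller amount at higher counts (-2.37 ± 1.14). In the 52 calls, the allele that was rarer in the plasmid DNA was the lower one in 40 (76.9%, exact 95% interval 63.2 to 87.5), against 55.2% of all tested variants.

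The number of SH-SY5Y calls was 349 with DESeq2 and fell to 30, 34 and 33 without replicate 1, 2 or 4. Of 29 named SH-SY5Y calls, those of PDLIM5, STAT6, TTYH3, SLC39A8, SFTA2 and ADH1C passed in every alternative in which they were tested, while limma on log2 ratios ended 14, among them GNE and LMO7 and nearly all of the rare-allele variants above. The limma effects of the 14 kept their sign at smaller sizes, such as 4.31 for GNE (adjusted p = 0.0686), 3.32 for LMO7 (0.0669), -3.98 for TANC2 (0.217), -3.75 for GIGYF1 (0.167) and -3.47 for BRD2 (0.388). With 1 replicate left out, AATK (2.92 to 3.61) and GIGYF1 (-4.46 to -3.66) lost the call whichever replicate it was. The call of ATG13 was lost without replicate 1, 2 or 3 (1.39 to 1.74 over the 6 fits), that of C16orf62 without 1, 2, 5 or 6 (1.30 to 1.75), that of ZFP64 without 1 or 5 (-2.69 to -2.07) and that of SPTSSB without 1, 2, 4 or 5 (1.59 to 1.98). Calls were also lost for KCTD2 without 1, 2, 4 or 5 (3.37 to 4.12), RPS6KL1 without 1, 3, 4, 5 or 6 (-5.69 to -4.39), RDH13 without 1, 2 or 6 (-4.76 to -4.19) and CDHR5 without 1, 2 or 3 (-4.56 to -3.67). The same held for ADAMTSL4-AS1 without 1, 2, 4 or 5 (-4.53 to -3.82), MTA3 without 1, 2, 4 or 6 (-4.14 to -3.32) and SLC9B1 without 2 (-6.11 to -4.44).

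In microglia the largest higher effect among named variants was at SLC39A8 rs151371 G>A, where the A allele was 6.84-fold higher (log2 2.77 ± 0.34, n = 6, edgeR adjusted p = 1.46e-12). TTYH3 rs114755822 G>A (2.34 ± 0.44), C16orf62 rs116582019 C>A (1.99 ± 0.46) and ATG13 rs7113453 G>A (1.71 ± 0.21) were also higher. So were TRIM26 rs7843 T>C (2.16 ± 0.68), in the gene for a ubiquitin ligase of the MHC region, MAML1 rs115034831 G>A (2.68 ± 1.74), in the gene for a Notch coactivator, and ITGA8 rs878321 C>T (1.63 ± 0.36), in an integrin gene. The alternative allele was lower for SNX8 rs62442512 C>T (-1.98 ± 0.53), a sorting nexin gene, ZFP64 rs79646797 G>T (-1.92 ± 0.90), MAP2K5 rs12900208 C>G (-1.72 ± 0.40), in the gene for a kinase of the ERK5 cascade, AGK rs6943245 C>T (-1.74 ± 0.65), which encodes a mitochondrial lipid kinase, and ADH1C rs2298753 A>C (-1.53 ± 0.23). VPS13C rs2059471 T>G, in a lipid transfer protein gene known from Parkinson disease, was lower as well (-1.51 ± 0.35).

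In all, 226 of 13017 variants passed in microglia, 119 higher and 107 lower, with a median size of log2 0.88, and 1221 had an unadjusted p under 0.05. The rarer allele in DNA was the lower one in 46.0% of these calls. Further named higher effects were DUSP6 rs704073 C>T (log2 1.83 ± 0.68), a phosphatase of ERK, RBM26 rs3187338 G>A (1.78 ± 0.30), TXNRD2 rs58210408 G>T (1.74 ± 0.58), the mitochondrial thioredoxin reductase, and PTGIS rs5594 C>T (1.65 ± 0.63), prostacyclin synthase. Further lower effects were BRD1 rs74426391 C>T (-2.54 ± 2.08), HEG1 rs115858188 G>A (-2.07 ± 0.47), PARD6G rs8099311 T>C (-1.81 ± 0.44), BIN3 rs113091101 C>G (-1.59 ± 0.94) and RGL2 rs183461458 C>G (-1.56 ± 0.64). BRD1 lost its call with limma (-1.63, adjusted p = 0.748) and without replicate 1, 2 or 5 (-3.08 to -2.19 over the 6 fits). DESeq2 gave 352 calls, while leaving out a replicate gave 167 to 192.

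Grouped by the fixed lists, alcohol and aldehyde metabolism genes had 3 of 15 tested variants past the threshold in microglia, all with a lower alternative allele (4 adjusted over the list alone). These were ADH1C rs2298753 A>C, ADH4 rs2602895 G>A (log2 -1.23 ± 0.21) and ADH4 rs2851249 A>G (-0.78 ± 0.10), both genes of alcohol dehydrogenases. Of the other variants 1.72% passed (odds ratio 14.3, Fisher's exact test adjusted p = 0.0302). The 3 variants lie in 2 genes, and the test treats variants as independent. No other list passed in microglia (adjusted p from 0.328 to 1), and none passed in SH-SY5Y (0.705 to 1), where 1 of the 15 alcohol list variants was called (2 adjusted over the list alone). HLA and antigen presentation genes had 10 of 342 variants called in microglia, 5 higher and 5 lower (adjusted p = 0.344; 11 adjusted over the list alone), including HLA-DPA1 rs3077 T>C (1.08 ± 0.36) and HLA-DPB1 rs9277559 T>C (-0.96 ± 0.17). None of 341 was called in SH-SY5Y. Monoamine, opioid, cannabinoid and cholinergic genes had 3 of 52 called in microglia, all at a single SNP, CHRNB4 rs80037964, whose A, G and T alleles were each higher than the shared C reference (0.71 ± 0.24, 0.83 ± 0.29 and 0.78 ± 0.28; adjusted p of the list = 0.328). CHRNB4 encodes a nicotinic acetylcholine receptor subunit. In SH-SY5Y the A allele was the 1 call of that list (0.72 ± 0.40), lost without replicate 3, 4, 5 or 6 (0.64 to 0.84).

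Cytokine and innate immune genes had 4 of 189 variants called in microglia, among them STAT6 (0.92 ± 0.31) and TRIM31 rs28400887 G>A (-0.80 ± 0.13), and 1 in SH-SY5Y. The STAT6 call in microglia ended when reads estimated as shared with SH-SY5Y libraries were subtracted (log2 0.49, edgeR adjusted p = 0.0808). Parkinson disease genes had 4 of 356 called in microglia, 1 higher and 3 lower, including DGKQ rs4690326 T>G (-1.36 ± 0.63), and 2 in SH-SY5Y. Alzheimer disease genes had 2 of 200 in microglia, CTSB rs71518539 G>A (1.48 ± 0.46), the gene for the lysosomal protease cathepsin B, and IQCK rs227764 C>A (-0.66 ± 0.29), and 1 in SH-SY5Y. Psychiatric risk genes had 3 of 370 in microglia, among them TSNARE1 rs72687374 G>A (1.09 ± 0.43) and ZKSCAN4 rs75876212 T>C (-1.48 ± 0.23), and 1 of 371 in SH-SY5Y. Lysosome and autophagy genes had 2 of 149 in each line, ATG13 and CTSB, both higher. GRIN2B, an NMDA receptor subunit gene on the GABA and glutamate list and the autism and epilepsy list, had both of the calls of each in microglia, rs4764006 A>G (0.65 ± 0.28) and rs79882245 G>A (1.05 ± 0.58). Zinc finger genes had 4 of 552 called in microglia and 0 of 556 in SH-SY5Y (adjusted p = 0.328 and 0.705). No variant of the ALS and frontotemporal dementia, RNA-binding, synaptic vesicle or histone lists was called in either line, and none of the GABA and glutamate or the autism and epilepsy lists in SH-SY5Y. Adjusted over the list alone, SH-SY5Y had 3 calls for Parkinson disease, 4 for psychiatric risk and 1 for synaptic vesicle genes. The counts of all other lists were the same adjusted over the list alone as over all variants. In SH-SY5Y the calls of CTSB (1.16 ± 0.55), TSNARE1 (0.82 ± 0.43) and VPS13C (-1.16 ± 0.59) lay near the threshold (edgeR adjusted p = 0.0199, 0.0381 and 0.0342). Most fits with 1 replicate left out lost them, with effects of similar size. CTSB lost its call without replicate 2, 3, 4, 5 or 6 (1.03 to 1.33), TSNARE1 without 1, 2, 4, 5 or 6 (0.75 to 0.95) and VPS13C without 1, 3, 5 or 6 (-1.32 to -1.01).

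The direct comparison of the cell lines asks where the allelic effect itself differed. The G allele of STAT6 rs324015 was higher by log2 3.39 in SH-SY5Y and by 0.92 in microglia, a difference of log2 -2.47 (microglia minus SH-SY5Y, edgeR adjusted p = 4.48e-10). The G allele of PDLIM5 rs1139697 was 13.0-fold higher in SH-SY5Y and 1.54-fold in microglia (0.62 ± 0.45, not past the threshold there), a difference of -3.08 (adjusted p = 5.38e-10). The difference also passed for GNE rs7048468 (difference -4.28, adjusted p = 0.0171), LMO7 rs9544054 (-3.54, 0.0277), SPTSSB rs163327 (-2.06, 0.0171) and FBLN1 rs74388276 (5.00, 0.00365). These 6 of 12989 variants passed, 1 with a more positive and 5 with a more negative effect in microglia. In SH-SY5Y the reference oligos of GNE and LMO7 had 13 and 37 RNA counts over the 6 libraries, and FBLN1 had few alternative counts, as given above. The activity differences of the GNE and LMO7 oligos given below rest on the same counts. STAT6 and PDLIM5 kept the call with each replicate left out. FBLN1 lost it without replicate 1 or 3 (4.55 to 5.60), GNE and LMO7 without 1, 3, 4 or 5 (from -4.59 to -3.97 and from -3.73 to -3.29) and SPTSSB without 1, 2, 3 or 4 (-2.29 to -1.70). The number of variants was 2 without replicate 1 or 3 and 29 with DESeq2, and was 3 with at least 200 DNA counts.

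**Figure D2:**
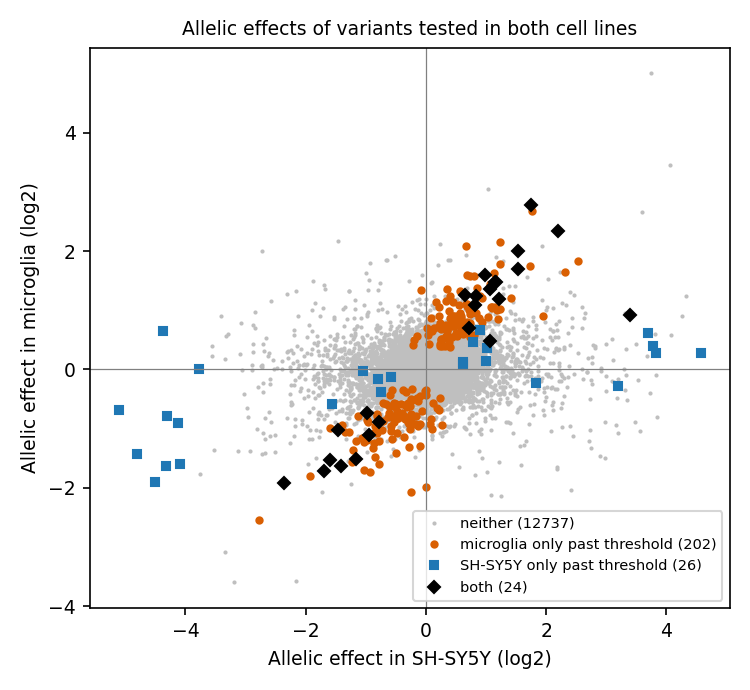
Allelic effect (log2) in microglia against SH-SY5Y for variants tested in both lines, 1 point per variant. Diamonds are the 24 variants past the threshold in both, circles the 202 in microglia only, squares the 26 in SH-SY5Y only and grey points the 12737 in neither; the diamonds all lie in the quadrants of equal sign.

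Across the 12989 variants tested in both lines, allelic effects correlated with Pearson's r = 0.199 and Spearman's rho = 0.164 (permutation p = 1e-05 for each, the smallest that the resamples can give). The correlation is across variants, which are not independent replicates. It was 0.157 after subtraction of reads estimated as shared between same-numbered libraries. In both lines 24 variants passed, all with the same sign, and 22 after that subtraction, which ended the microglia call of STAT6. Of the 24, 15 were higher in both, where independent lists would share 0.247, and 9 were lower in both, where they would share 0.189. Of the 226 microglia calls, 212 had the same sign in SH-SY5Y. By the naming rule 13 variants passed in both lines: higher for SLC39A8, TTYH3, C16orf62, ATG13, CTSB, SFTA2 (1.18 ± 0.21 in microglia), TSNARE1, STAT6 and CHRNB4, and lower for VPS13C, ADH1C, MAP2K5 and ZFP64. Apart from STAT6, the difference between lines did not pass for any of them.

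**Figure D3:**
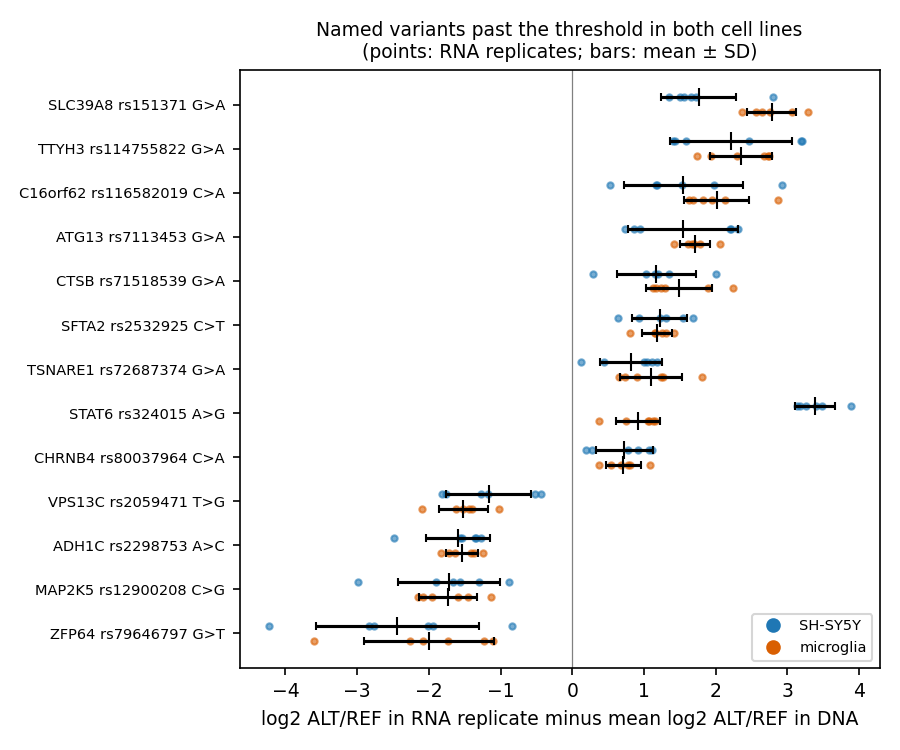
Allelic effect per RNA replicate (log2 ratio of alternative to reference, minus the mean of the DNA libraries) for the 13 named variants past the threshold in both lines. Points are the 6 replicates of each line and bars the mean ± SD; STAT6 is the variant with the widest gap between lines.

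Reporter activity compares each reference oligo in RNA with its own plasmid DNA. In SH-SY5Y the fragment of TREML2 with the A allele of rs112522404 (chromosome 6, 41189749 to 41201149), a gene of the TREM receptor cluster, was above the typical oligo by log2 3.39 ± 0.16 (n = 6). Fragments of FBXL18 (rs182946436, 1.83 ± 0.58), DSG3 (rs181938639, 1.47 ± 0.72), a desmosomal cadherin gene, MOG (rs2535243, 1.44 ± 0.35), a myelin protein gene, WDR27 (rs16888021, 1.25 ± 0.28) and TRIM56 (rs13229423, 1.24 ± 0.36) followed. Among the lowest, the C1orf106 fragment (now INAVA, rs296523) was at log2 -5.02 ± 0.86, on 19 RNA counts over the 6 libraries. Other low fragments were rare in the plasmid pool. GIGYF1 rs221792 had 0 RNA counts and was at least 16.4-fold lower. ARHGAP27 rs7613 was 46.8-fold lower (95% interval 13.0 to 386), SLC41A1 rs1341249 44.4-fold (12.3 to 366) and CD40 rs11569331, in an immune receptor gene, 48.4-fold (8.69 to 1912). Of 10973 oligos 952 passed, 454 higher and 498 lower (47.7% higher). With total counts in place of TMM, 294 were higher and 570 lower (34.0% higher). DESeq2 called 1642. GIGYF1 and CD40 lay near the DNA filter and were each tested in only 2 of the fits with a replicate left out. GIGYF1 lost its call without replicate 2 (adjusted p = 0.0692) and CD40 without replicate 1 (0.0643).

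In microglia 2286 of 10966 reference oligos passed, 936 higher and 1350 lower. The highest were fragments of HEG1 (rs115858188, log2 1.37 ± 0.40), FBXL18 (1.04 ± 0.38), CUL3 (rs10498161, 1.03 ± 0.42), a ubiquitin ligase scaffold gene, PPP2R2D (rs117262064, 0.94 ± 0.12), PGM2L1 (rs7941916, 0.94 ± 0.19) and BBS9 (rs6462474, 0.94 ± 0.50). The HEG1 oligo had a mean of 58.7 DNA counts. It is the reference of the lower HEG1 allelic effect given above, so the 2 results share its counts. HLA-DPB1 rs9501257 was 30.1-fold lower (95% interval 10.3 to 146) and ELMOD2 rs3104104 25.4-fold (8.69 to 123). Both were rare in the plasmid pool, with means of 25.7 and 21.7 DNA counts and 3 RNA counts each. The zeros of rare oligos described below bear on them as well. Fragments of HS6ST3 (rs12583999, -3.90 ± 1.33), NRTN (rs116386264, -3.69 ± 1.69), the gene for the growth factor neurturin, and NMNAT2 (rs579217, -3.02 ± 1.49), an axonal NAD synthesis gene, were lower as well, on 18, 35 and 44 RNA counts over the 6 libraries. CUL3 lost its call without replicate 5 (adjusted p = 0.131).

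Activity differed between the lines most clearly for TREML2 rs112522404, which was at log2 3.39 ± 0.16 in SH-SY5Y and 0.83 ± 0.25 in microglia (difference log2 -2.58, adjusted p = 1.02e-14). The TMEM179B fragment (rs2584916) was at 0.40 ± 0.19 in SH-SY5Y and -1.62 ± 0.31 in microglia (difference -2.04, adjusted p = 1.39e-07). The ARHGAP40 fragment (rs6027039) was higher in SH-SY5Y (1.07 ± 0.28) and lower in microglia (-0.42 ± 0.19), and the TAF6 fragment (rs13309), from a gene of the general transcription factor TFIID, was at 0.56 ± 0.46 in SH-SY5Y and was 0.499 of the typical oligo in microglia (SD of log2 0.45). Fragments that were lower in SH-SY5Y than in microglia came from ATXN3, the deubiquitinase gene of Machado-Joseph disease (rs34351382, -3.83 ± 0.84 against -0.13 ± 0.57, and rs11621770, -3.79 ± 1.59 against -0.25 ± 0.40), CARF (rs6736831, -3.45 ± 0.41 against -0.32 ± 0.41), GNE (rs7048468, -4.17 ± 0.66 against -0.22 ± 0.69), DDX6 (rs200752984, -3.19 ± 1.30 against 0.18 ± 0.32), an RNA helicase gene, LMO7 (rs9544054), JAM3 (rs7936421) and CAST (rs17086651). In SH-SY5Y these values rest on few RNA counts over the 6 libraries: 15 and 24 for ATXN3, 43 for CARF, 13 for GNE, 18 for DDX6, 37 for LMO7 and 8 for JAM3. The CAST fragment was 29.9-fold lower there on 2 RNA counts (95% interval 8.26 to 246, counting error only). ADAMTS14, RASIP1, BATF3 and DRC3 fragments were lower in microglia than in SH-SY5Y.

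In all 103 of 10948 oligos passed, 22 with a higher and 81 with a lower activity in microglia relative to SH-SY5Y. DESeq2 called 217, and 41, 53, 51, 66 and 61 passed without replicate 1, 2, 4, 5 or 6. TREML2, TMEM179B, ARHGAP40, TAF6, CARF, GNE and the ATXN3 fragment at rs34351382 kept the call with each replicate left out. JAM3 lost it whichever replicate was left out (differences from 4.18 to 4.86), BATF3 without 1, 2, 4, 5 or 6 (-1.52 to -1.27), LMO7 without 1, 2, 3, 4 or 5 (2.72 to 3.04) and CAST without 1, 2, 3, 4 or 6 (4.08 to 5.68). ADAMTS14 lost it without 1, 2 or 5 (-2.26 to -1.72), RASIP1 without 1, 2 or 4 (-1.79 to -1.37), DDX6 without 1 or 6 (3.11 to 3.59), ATXN3 rs11621770 without 1 or 4 (3.22 to 4.43) and DRC3 without 5 (-1.51 to -1.09).

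**Figure D4:**
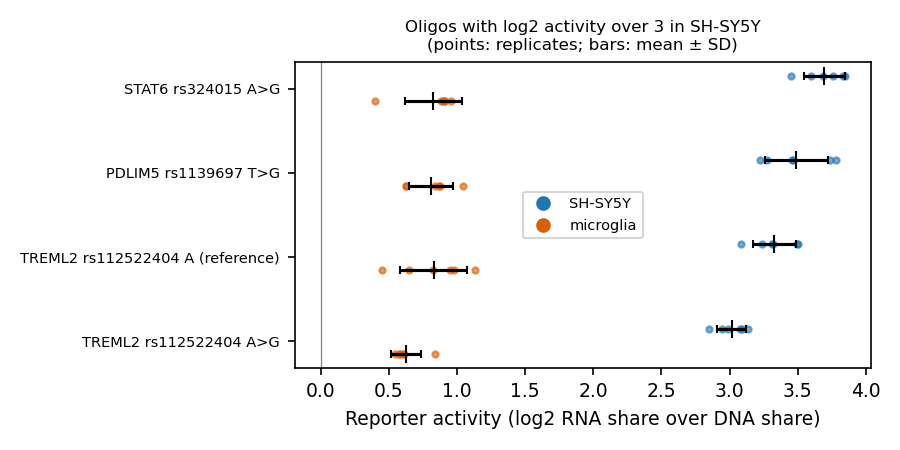
Reporter activity (log2 RNA share over DNA share) of the 4 oligos above log2 3 in SH-SY5Y, among oligos with a mean of at least 100 DNA counts. Points are the 6 replicates of each line and bars the mean ± SD; in microglia the same oligos lie between 1.54-fold and 1.78-fold above their DNA share.

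Allelic effects were also compared between variants that gain and variants that lose a G or C. In SH-SY5Y the mean effect was 0.01 ± 0.62 (SD across 4461 variants that gain) and 0.00 ± 0.64 (6061 that lose), and the difference did not pass (0.0059, permutation p = 0.635, adjusted 0.77). In microglia the difference was -0.0021 (permutation p = 0.77, adjusted 0.77; 4454 and 6061 variants).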

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

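The tests of library depth, of read sharing, of a shared plasmid preparation and of 4 oligos high in SH-SY5Y RNA were chosen only after the result was seen. Those on rare oligos were written before.

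In the 52 SH-SY5Y calls, the allele rarer in the plasmid pool was the lower one in 40, and 14 of the 52 had a rarer allele with under 100 DNA counts. A lower RNA depth in SH-SY5Y is excluded, since its RNA libraries were deeper than those of microglia (ratio of means 1.59). Few reporter molecules behind rare oligos met the prediction set for them. Among oligos with 10 to 50 DNA counts, 17.4% of SH-SY5Y RNA values were 0, against 0.00198% from counting error alone. In microglia the values were 9.92% against 0.0202%. At 50 to 200 DNA counts, 0.615% were 0 in SH-SY5Y and 0.268% in microglia. Low activity or a loss of rare oligos would also give zeros beyond counting error. Microglia exceeded counting error too, although the rarer allele was the lower one in only 46.0% of the microglia calls. The test therefore cannot tell few molecules from these other causes. A systematic loss of rare oligos as the whole cause met the bound set against it, with a margin of little more than 1 SD. The RNA share of oligos with 10 to 50 DNA counts was 0.854 ± 0.0434 (SD, n = 6) of the DNA share, against 0.987 ± 0.0167 in microglia. At 50 to 200 DNA counts it was 0.937 ± 0.0143, against 0.995 ± 0.00558 in microglia. A partial loss was thus measured in SH-SY5Y, and how far it accounts for the calls was not tested. Few molecules, a partial loss or a real effect may lie behind the largest lower effects in SH-SY5Y, such as those of BBS9, RPS6KL1 and CDHR5. The same holds for the low activities there of rare fragments such as those of GNE, ATXN3, DDX6, JAM3 and CAST. These causes were not told apart. The GNE and ATXN3 rs11621770 fragments had means of 53.3 and 73.8 DNA counts, in the range where 0.615% of values were 0. The part of few molecules in the calls with higher counts was not tested, and a difference between the cell lines stays open as untested.

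RNA libraries of the 2 cell lines with the same replicate number deviated together. Their log2 allele ratios over 11783 variants had a mean correlation of 0.0771, and each of the 6 correlated best with its own number (exact pairing test, p = 0.00139, the smallest that 720 pairings can give). The other correlations given here are also of allele ratios, while the slope and the shared amount use the counts of 22549 oligos. A plasmid preparation shared by same-numbered replicates is excluded as the main source of these RNA deviations, since it would move the DNA alike, and SH-SY5Y RNA and same-numbered microglia DNA correlated at -0.00353 (from -0.0242 to 0.00775), although a small part stays open, since SH-SY5Y DNA and microglia RNA correlated at 0.00364 (exact pairing p = 0.272) with a slope of 0.0308 ± 0.0327 (SD, n = 6, exact pairing p = 0.00972). The DNA libraries of the 2 lines did deviate together by number, at a mean correlation of 0.0446 (6 of 6 best with their own number, exact pairing test, p = 0.00139), and whether they share plasmid or reads stays open. Reads of the SH-SY5Y RNA library counted in microglia met the prediction set for them. The deviations put the shared amount at 2.43% ± 0.237 (SD, n = 6) of the SH-SY5Y count. Among oligos with a mean of at least 100 DNA counts, each of the 4 above log2 3 in SH-SY5Y had a microglia excess of at least that. The smallest excess was 3.51%. A real activity of these oligos in microglia would meet this prediction as well, so it cannot tell shared reads from such activity. The excess is above the estimated share, so the 4 oligos kept a log2 activity of 0.24 to 0.45 in microglia after subtraction, and a common handling of same-numbered RNA libraries other than shared reads was not tested.

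The 22553 oligos with a mean of at least 100 DNA counts were ranked by RNA over DNA share in SH-SY5Y, and those with fewer were not. Among the ranked oligos 4 stood far above the others. They were the G allele of STAT6 rs324015 (13.0-fold over its DNA share), the G allele of PDLIM5 rs1139697 (11.2-fold) and both alleles of TREML2 rs112522404 (A 10.0-fold, G 8.09-fold). The next ranked oligo, FBXL18 rs182946436 with the A allele, was at 3.47-fold. Extra plasmid of these oligos in SH-SY5Y is excluded, since their DNA share was at most 1.12 times that in microglia. A few over-represented molecules in single libraries are excluded too, since the largest SD over replicates was 0.230, below the median SD of 0.479 over all ranked oligos. RNA made from a source other than the counted plasmid, and a true effect of the fragment in neuroblastoma cells, stay open as untested.

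Differences between cell lines, each given as microglia minus SH-SY5Y on the log2 scale and past the test of the difference, were measured for the allelic effects of GNE (-4.28), LMO7 (-3.54), PDLIM5 (-3.08), STAT6 (-2.47), SPTSSB (-2.06) and FBLN1 (5.00). For activity, the values below 0 were those of TREML2 rs112522404 A (-2.58), TMEM179B (-2.04), ADAMTS14 (-1.97), TAF6 (-1.57), RASIP1 (-1.55), ARHGAP40 (-1.51), BATF3 (-1.41), DRC3 (-1.29) and WDR27 rs16888021 (-0.85). The values above 0 were those of CAST (4.64), JAM3 (4.55), GNE (3.94), ATXN3 rs34351382 (3.68), ATXN3 rs11621770 (3.53), DDX6 (3.35), CARF (3.12), LMO7 (2.88) and PPP2R2D (0.62).

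A single replicate lay apart from the other 5 in 19 of 165 sets of replicate values, where chance gives about 8.25 for normally distributed values. In the SH-SY5Y allelic effects the replicate apart had log2 8.24 for LMO7 (replicate 6; the others 2.20 to 4.27), 3.53 for SPTSSB (replicate 6), 2.80 for SLC39A8 (replicate 3; the others 1.34 to 1.73), -5.92 for TANC2 (replicate 5), -5.73 for GIGYF1 (replicate 5) and -2.49 for ADH1C (replicate 3). It had 5.98 for MAML1 (replicate 5), 2.18 for BRD1 (replicate 4; the others -4.18 to -3.21), and 1.66 for AGK (replicate 1), none of which passed the threshold in SH-SY5Y. In SH-SY5Y activity it had -1.57 for CD40 (replicate 3), -1.84 for ELMOD2 (replicate 3), -5.87 for DDX6 (replicate 5), -7.18 for LMO7 (replicate 6) and 0.77 for TMEM179B (replicate 1). In microglia it had 3.83 for the allelic effect of AATK (replicate 5), 2.33 for that of ITGA8 (replicate 6), 0.85 for the activity of HEG1 (replicate 3) and -0.97 for that of ATXN3 rs11621770 (replicate 6). In SH-SY5Y the CD40 and ELMOD2 oligos had only 1 and 2 RNA counts over the 6 libraries, DDX6 had 18 and LMO7 had 37. At such counts a replicate value depends strongly on the pseudocount of 0.5, so a replicate can lie apart for that reason alone.

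Oligos with no DNA count entered no test, yet 25 of 454 such oligos in SH-SY5Y and 28 of 462 in microglia had more than 3 RNA counts. Of the 35 found in either line, 32 had RNA counts in all 12 RNA libraries and at most 1 count over all 12 DNA libraries. Why their DNA counts are missing was not tested. Whether tested oligos were also undercounted in DNA, which would raise their RNA over DNA values, was not tested either. The G allele of WDR27 rs75504333 had 13216 RNA counts in SH-SY5Y and the T allele of BNIP3L rs17055200 had 5606 in microglia.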

How the results depend on the processing

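The fits with at least 200 DNA counts, with robust empirical Bayes, with shared reads subtracted and with a replicate left out of the differences between lines were chosen only after the result was seen. No effect of a named variant or oligo that passed the threshold changed sign under any alternative. With DESeq2 the allelic calls were 349 in SH-SY5Y and 352 in microglia, against 52 and 226 with edgeR; its activity calls in SH-SY5Y were 1642 against 952, and its differences were 29 against 6 for allelic effects and 217 against 103 for activity. A minimum of 200 DNA counts left 3 differences in allelic effect. Leaving out a replicate gave 30 to 45 allelic calls in SH-SY5Y, 167 to 192 in microglia, 2 to 8 differences in allelic effect and 41 to 87 in activity; activity calls ran from 706 to 812 in SH-SY5Y and from 1926 to 2041 in microglia. These fits hold fewer libraries, and the cause of the other shifts was not tested. All other numbers of calls stayed within 1.5 times the edgeR number, apart from the fits with a block described below, the correlation between lines stayed past its test (0.157 to 0.308), and the alcohol and aldehyde list kept its call at 50 DNA counts (adjusted p = 0.0325). Of the named calls, 6 of 29 allelic calls in SH-SY5Y and 25 of 28 in microglia passed in every alternative in which they were tested, as did 9 of 12 and 11 of 12 activity calls, 2 of 6 differences in allelic effect and 5 of 16 in activity.

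Replicate numbers are shared by the groups, and the labels do not say that they pair libraries. The allele ratios of same-numbered DNA and RNA libraries correlated at a mean of 0.0291 in SH-SY5Y (4 of 6 best with their own number) and 0.0353 in microglia (6 of 6). These values are small, but the exact pairing test gave p = 0.00139 in each line, the smallest that 720 pairings can give. As a hint from the data, same-numbered libraries are thus not fully independent, while the main fits treat them as independent. With the replicate number as a block, allelic calls were 36 in SH-SY5Y and 245 in microglia, activity calls 821 and 2323, and differences 3 for allelic effects and 56 for activity. Among the named differences, the block ended the calls of GNE (log2 -4.27 with the block, -4.28 without), LMO7 (-3.61 and -3.54) and SPTSSB (-2.09 and -2.06) for allelic effects. For activity it ended those of GNE (4.02 and 3.94, adjusted p with the block 0.0507), ATXN3 rs34351382 (3.71 and 3.68, 0.0690), DDX6 (3.46 and 3.35), LMO7 (3.10 and 2.88), CAST (4.84 and 4.64), JAM3 (4.93 and 4.55), ADAMTS14 (-1.79 and -1.97) and BATF3 (-1.34 and -1.41). The values stayed about as large, and the adjusted p moved past the threshold. In SH-SY5Y it ended the allelic calls of KCTD2, AATK, BBS9, RPS6KL1, RDH13, ADAMTSL4-AS1, GIGYF1, MTA3, CHRNB4 and TSNARE1, and the activity calls of GIGYF1 and CD40 were among those it ended. The smallest effects that could be seen were set by replicate spread more than by depth: SH-SY5Y RNA was deeper than microglia RNA and more variable, and recovered 10% of simulated allelic changes of log2 1, against 76% in microglia.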

Other observations

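The comparison of activity calls with the gene lists, that of activity between lines and the count of G or C changes among called variants were chosen only after the result was seen; the other groupings of the libraries were planned.

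Reference oligos from histone genes were called for activity 6 times among 37 in SH-SY5Y, 5 higher and 1 lower, and 8 times among 37 in microglia, 7 higher and 1 lower (adjusted p = 0.657 and 0.915 for the share called, Fisher's exact test). Oligos of RNA-binding and microRNA pathway genes had 10 of 49 called in SH-SY5Y and 16 of 49 in microglia (adjusted p = 0.125 and 0.428). Alzheimer disease genes had 42 of 154 oligos called in microglia, 10 higher and 32 lower (adjusted p = 0.428), and lysosome and autophagy genes 25 of 110, 7 higher and 18 lower (0.915). HLA and antigen presentation genes had 74 of 299 called in microglia, 30 higher and 44 lower (0.484). No list passed in either line.

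Activity of reference oligos correlated between the lines with Pearson's r = 0.596 and Spearman's rho = 0.494 across 10948 oligos, which are not independent replicates. Allelic effects correlated with r = 0.199 across all variants tested in both lines and with 0.864 across the 226 called in microglia, a set chosen by the microglia test itself. Both lines called 230 oligos higher, where independent lists would share 38.8, and 417 lower, where they would share 60.7. Only 3 of the 650 called in both had opposite signs, among them that of ARHGAP40 rs6027039.

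Among the microglia allelic calls, variants that gain a G or C were higher in 35 and lower in 44, and variants that lose a G or C were higher in 68 and lower in 43 (odds ratio 0.505, Fisher's exact test, unadjusted p = 0.0266). With at least 50 DNA counts the odds ratio was 0.572 (Fisher's exact test, p = 0.0624). In SH-SY5Y the counts were 5 and 9 against 15 and 13 (odds ratio 0.490, Fisher's exact test, p = 0.338).

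Other groupings of the same libraries were fitted to ask whether chance could give as many calls. Of 100 groupings of the 12 libraries of a line, 1, the real one, gave as many allelic calls in SH-SY5Y (52; the highest other 0) and in microglia (226; the highest other 11), and the same held for activity (952 and 2286; the highest other 0 in both). Of 40 groupings between cell lines, 1, again the real one, gave as many differences in allelic effect (6; the highest other 1) and in activity (103; the highest other 4). The calls thus followed the real labels. Every other grouping mixed DNA with RNA, or the cell lines, so real differences added to the spread within its groups. Such groupings tend to give few calls for that reason, and they cannot show how many of the real calls are false.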
